A study of Mus musculus with 3 samples.

How the data were processed

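Lineage-negative, Sca1-positive, Kit-positive bone marrow cells (LSK cells, the compartment that holds stem cells and multipotent progenitors) from 2 mice labelled Helios-deficient and 2 wild-type mice were profiled together. Each mouse carried its own hashtag antibody, and the cells also carried oligonucleotide-tagged antibodies against CD41, CD48, CD150 and Flt3 (CD135). Per the labels, 2500 cells per mouse were pooled and loaded in 1 droplet run with a 3 prime chemistry. Messenger RNA, antibody tags and hashtags were then sequenced as separate libraries.

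The deposited matrix holds raw UMI counts for 31053 genes, 4 antibody tags and 4 hashtags in 4108 barcodes. Its values are whole numbers and the cell totals differ, so no scaling had been applied. The matrix header gives software version 3.0.2, and the submitters' processing notes name Cell Ranger without a version, Seurat 3.0.0 and genome build mm10. A deposited table gives the authors' hashtag call of each barcode: 3842 calls of a single mouse, 231 doublets and 35 without a hashtag. A second deposited list names the 3470 barcodes that the authors kept. The filter behind that list is not stated. Every kept barcode had a single-mouse call and a mitochondrial UMI share of at most 5.00%. Of the 372 single-mouse barcodes left out, 304 had a share of 5% or more, and 32 of the other 68 had more UMIs than the largest kept cell, at 32870. No cell annotation was used here.

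The 3470 kept cells were used. Hashtags 1 and 2 marked the Helios-deficient mice, and hashtags 3 and 4 the wild-type mice, per the labels. Doublets between mice had been called by hashtag and were absent from the kept cells. No doublet caller was run on the rest. From the doublet calls and the mouse shares, 82.8 doublets within a mouse were expected among the single-mouse barcodes (2.16%). The mouse was the replicate (n = 2 per genotype), and all 4 mice shared 1 run, so there was no batch term.

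UMI counts were summed per mouse and tested with edgeR 4.0.16 (quasi-likelihood test, robust, TMM scaling, its default filter on low counts) in R 4.3.3. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. Log2 fold changes are Helios-deficient over wild type, the standard error was derived from the fold change and its F statistic, and CPM is a mouse's UMI count scaled by its library total. The procedure was tested on simulated counts drawn from the real means and library sizes, with 200 of 11450 genes changed. It recovered 79 of 100 genes changed 1.5-fold and 100 of 100 changed 2-fold, with 4 false calls. The changed genes all had a mean above 10 CPM, and each gene was drawn with the dispersion that edgeR fitted to its mean level. These values hold for counts simulated this way, not for every gene tested, and recovery at lower CPM was not measured. The real calls moved with the settings, as given further on.

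Before the data were examined, 17 gene lists, cell type markers and the rule for named genes were fixed. The rule takes Ikzf2 and the genes of the 4 antibody targets. It adds the 10 largest rises and 10 largest falls among genes past 0.05 with separated mice and a mean CPM of at least 10, up to 4 members per list with the smallest p, and within a class the 5 largest rises and falls. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests a list on its own. The lists were megakaryocyte and platelet, megakaryocyte-erythroid transcription factors, erythroid, lymphoid priming, granulocyte-monocyte, stem cell, stem cell aging, S phase, G2 and M phase, immediate early and dissociation stress, interferon response, NF-kB targets, MHC class II, p53 targets, MYC and nucleolar, oxidative phosphorylation, and the Ikaros family.

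Cells were clustered on Pearson residuals (theta 100) of 1500 variable genes, reduced to 30 components with 20 neighbours per cell. Cell cycle list genes, sex-linked genes and genes called between genotypes were left out of this step. Cell cycle genes still led cluster 6 and stood among the leading genes of the myeloid-primed-like cluster, so the cell cycle was not removed from the clusters. Leiden clustering at a resolution of 0.5 (leidenalg 0.10.2, igraph 0.11.9) gave 10 clusters. That resolution was chosen after seeing the data. A cluster took a name ending in "-like" where at least 3 fixed markers of a stem or progenitor type were 2-fold enriched and found in 10% of its cells. A marker of that type also had to be among the cluster's 10 leading genes, and no other type could have more there. Ties went to the type with more enriched markers. Otherwise the cluster kept its number. Cell counts per cluster were tested with edgeR, with the mouse total as library size. Genes were tested within the 5 classes with at least 50 cells in every mouse. A class by genotype interaction with mouse as a block was tested in the same tool.

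Shares of cells were compared after each cell was thinned to 5000 UMIs. This left out 43 and 52 cells of the Helios-deficient mice and 129 and 108 cells of the wild-type mice. Phases were called from the S and the G2 and M lists, scored against 50 control genes in each of 25 expression bins. Antibody tag counts were transformed to centred log ratios with a pseudocount of 1. Shares and tags were compared by two-sided exact permutation tests of 2 against 2 mice, whose smallest p is 0.333. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0 were used.

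Gene positions come from a RefSeq annotation of GRCm38.p6, the assembly named mm10, matched for 11142 of 11592 tested genes. Alternatives covered scaling (RLE), the count filter, the robust option, DESeq2 1.42.0, all single-mouse barcodes, thinned cells, equal cells per mouse, equal cells of each cluster, other resolutions and leaving out each mouse. Alternatives added after seeing the data were a resolution of 1, removal of cells with 3 or more UMIs of mature cell markers, of 30 granulocyte-monocyte cells (also in the interaction test) and of chromosome 1 genes, the stem cell and lymphoid clusters at the resolution of 1, these lymphoid clusters with a cluster led by Elane and Dntt, the interaction test without the myeloid-primed-like class and the lymphoid list without Ighm and Jchain. The list tests without cluster 9, taken as outside the sorting gate by its red cell markers, were also added then. For the gene calls that setting was planned. Where a genotype was left with 1 mouse, the fit assumes that this mouse varies like the others.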

Results

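The series asks what Helios, a zinc finger transcription factor of the Ikaros family encoded by Ikzf2, does in the mixed population of hematopoietic stem and progenitor cells. RNA and 4 surface proteins were measured in the same LSK cells of 2 mice labelled Helios-deficient and 2 wild-type mice. The kept cells numbered 557 and 824 in the Helios-deficient mice and 1175 and 914 in the wild-type mice. Total UMIs per mouse were 5729987, 8424677, 10317599 and 8364109 in that order, and median UMIs per cell were 8670, 8461, 7599 and 7627. All 4 mice expressed Xist, at 1839 to 2065 CPM, and had 0 UMIs of 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty), so sex did not differ between the genotypes.

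The targeted gene was measured first. Ikzf2 (ENSMUSG00000025997, chromosome 1, 69531207 to 69687351, mm10) stood at 73.8 and 82.7 CPM in the Helios-deficient mice and at 70.4 and 68.0 CPM in the wild-type mice. Its log2 fold change was 0.18 (SE 0.08, n = 2 per genotype) with an edgeR adjusted p of 0.46. In cluster 1, described further on, it was 0.48 with an adjusted p of 0.048. The labels do not say which part of the gene was deleted, and a 3 prime library can count transcripts that lack an internal part. The Ikzf2 level therefore checks neither the deletion nor the hashtag assignment, and the genotypes are used as labelled.

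Over all LSK cells, Helios-deficient mice had higher RNA of Selp (P-selectin, an adhesion receptor of platelets and endothelium), of the granule protease gene Ctsg and of Aldh1a1, a retinaldehyde dehydrogenase. The protease gene Ctse, the carboxylate transporter gene Slc16a11 and Sdc1 (syndecan-1) were lower. Selp (ENSMUSG00000026580) reached 30.4 ± 3.7 CPM against 9.92 ± 1.97 in wild type (mean ± SD, n = 2 mice each), a log2 fold change of 1.58 (SE 0.15, edgeR adjusted p = 5.6e-06). Ctsg (ENSMUSG00000040314) reached 187 ± 10.1 against 66.2 ± 6.2 CPM, and Aldh1a1 (ENSMUSG00000053279) 20.02 ± 2.08 against 7.31 ± 0.32 CPM. Ctse (ENSMUSG00000004552) was at 11.2 ± 3.5 CPM against 81.5 ± 1.1 in wild type, a log2 fold change of −2.81 (SE 0.13, adjusted p = 1.9e-09). Slc16a11 changed by −1.66 and Sdc1 by −1.45 on the log2 scale. Other large rises were in Ms4a3 (1.39), Anxa3 (0.96), Tgfbi (0.91), Gm4951 (0.85), Cavin2 (0.74), Meg3 (0.69) and Sfi1 (0.64).

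The remaining large falls included 3 genes within 3 Mb of Ikzf2 on chromosome 1. These were Rpe (66700797 to 66719805), which encodes an enzyme of the pentose phosphate pathway, Acadl (66830839 to 66863309), an enzyme of mitochondrial fatty acid oxidation, and Lancl1 (67000517 to 67038891). Rpe was at 14.6 ± 0.3 against 35.4 ± 2.5 CPM, Acadl at 44.9 ± 4.8 against 96.5 ± 2.1 CPM and Lancl1 at 22.0 ± 1.1 against 39.6 ± 1.6 CPM. Gm47283 (−0.98 on the log2 scale), Olfr1369-ps1 (−0.91), Zfp36 (−0.76) and Ccl3 (−0.73) were also lower. Within 10 Mb of Ikzf2, 3 of 69 tested genes were called (4.35%), against 85 of 11073 elsewhere (0.768%), a comparison chosen after these 3 genes were seen. Of the other 66 genes there, 5 lay below an unadjusted 0.05 (7.58%), against 9.58% of the uncalled genes elsewhere (Fisher's exact test, two-sided p = 0.833). Over chromosome 1 as a whole, 10 of 625 tested genes were called, against 78 of 10517 elsewhere (Fisher's exact test, two-sided p = 0.0312, 0.34 adjusted over chromosomes). For chromosome 1 beyond 10 Mb of Ikzf2 the odds ratio was 1.65 (95% interval 0.64 to 3.59). Ctse, Selp and Cavin2, among the largest changes, lie in that part of chromosome 1.

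In total, 92 of 11592 tested genes passed, 42 higher and 50 lower, and in all 92 both mice of a genotype lay on the same side of the other pair. Chance gives that order in 33.3% of unselected genes, and a test between genotypes selects for it. Without Helios-deficient mouse 1 the count was 306 and without Helios-deficient mouse 2 it was 565. DESeq2 called 35 genes, 33 of them among the 92, the fit without the robust option 57, the fit without a count filter 296, and equal cells of each cluster per mouse 44. Of the 20 genes with the largest changes, 13 passed without any 1 of the 4 mice. The call of Cavin2, Ccl3, Gm4951, Meg3, Sfi1, Tgfbi or Zfp36 ended without at least 1 mouse, at adjusted p from 0.069 to 0.287.

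**Figure D1:**
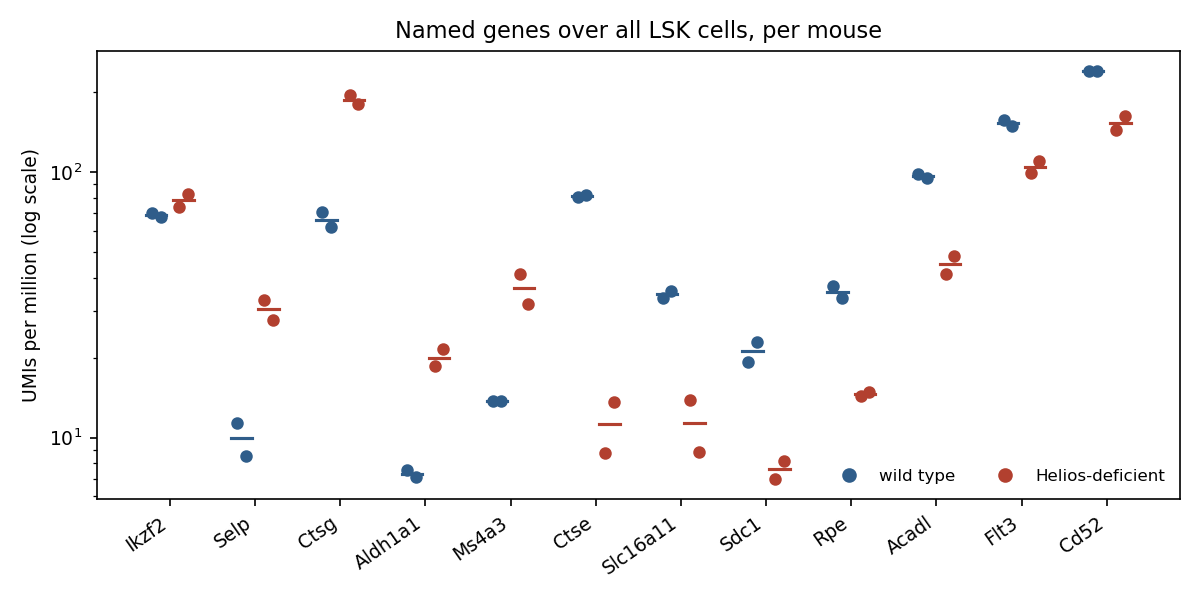
Library-scaled UMI counts (CPM, log scale) of 12 named genes in each of the 2 wild-type and 2 Helios-deficient mice, with a point per mouse and a line at each genotype's mean. Selp, Ctsg, Aldh1a1 and Ms4a3 lie higher and Ctse, Slc16a11, Sdc1, Rpe, Acadl, Flt3 and Cd52 lower in both Helios-deficient mice, while the Ikzf2 means are 78.3 and 69.2.

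Genes of lymphoid priming were lower in Helios-deficient LSK cells. Of 24 measured members 5 fell, namely Cd52, Flt3, Satb1, Lsp1 and Il12a, and 19 did not pass, and 6 fell when adjusted over the list alone. Flt3, the receptor tyrosine kinase of lymphoid-primed progenitors, stood at 105 ± 7.5 CPM against 153 ± 5.3 (log2 fold change −0.55, SE 0.07, adjusted p = 0.00028). The leukocyte surface glycoprotein gene Cd52 stood at 153 ± 12.9 against 240.0 ± 0.1 CPM, and the chromatin organiser gene Satb1 changed by −0.50 on the log2 scale. Dntt, which encodes the terminal transferase of early lymphocytes, differed by 0.01 (SE 0.34). The list's median log2 fold change was −0.37 (camera adjusted p = 1.3e-07, adjusted p = 0.384 with an estimated correlation), and −0.64 without Helios-deficient mouse 2. The list also holds the immunoglobulin genes Ighm, with 18674 UMIs in wild-type mouse 1 against 592 to 1214 in the other mice, and Jchain. Without both, the median was −0.32 (camera adjusted p = 9.7e-08, adjusted p = 0.384 with an estimated correlation). Lsp1 did not pass without wild-type mouse 1 (adjusted p = 0.311) or 2 (0.271). With equal cells of each cluster per mouse the list's median was −0.17 (camera adjusted p = 0.0197), and the share of lymphoid-primed-like cells was lower in these mice, as given with the clusters. Within lymphoid-primed-like cells the list did not fall. Its median there was −0.04 (camera adjusted p = 0.793, adjusted p = 0.867 with an estimated correlation), with 1 of 20 members called higher and 0 lower. That class was named by high RNA of list members such as Dntt, Ccr9 and Wfdc17, which favours a flat list there. The value therefore cannot separate a change in share from a change in priming. Helios-deficient mouse 1 had 50 cells in the class. In myeloid-primed-like cells the median was −0.20 (camera adjusted p = 0.0112, adjusted p = 0.352 with an estimated correlation).

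The granulocyte and monocyte list was higher. Of 19 measured members 5 rose (Ctsg, Ms4a3, Prtn3, Igsf6 and Mpo) and 14 did not pass, and adjusted over the list alone 6 rose and 2 fell. Prtn3, the gene of the neutrophil serine protease proteinase 3, stood at 843 ± 71.6 against 583 ± 31.6 CPM, and Igsf6 at 4.12 ± 0.38 against 1.11 ± 0.21 CPM. The median was 0.35 (camera adjusted p = 2.8e-04, adjusted p = 0.384 with an estimated correlation). It was 0.06 without Helios-deficient mouse 2 and 0.03 without wild-type mouse 2 (camera adjusted p = 0.0109 and 0.0198). The signal moved with few cells. A group of 30 cells led by Elane, Ly6c2 and Ctsg, with a median of 20134 UMIs against 7863.5 in the other cells, made up 1.44% and 1.58% of the Helios-deficient and 0.596% and 0.219% of the wild-type cells. Without them the list's median was −0.04 (camera adjusted p = 0.945), and Ms4a3 (0.49, adjusted p = 0.194) and Mpo (−0.27, 0.0518) no longer passed. Ctsg (0.78, adjusted p = 2.5e-05) and Prtn3 (0.39, 0.0047) still did.

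The stem cell list and the list of genes tied to stem cell aging were higher by camera, with few members called. In the stem cell list of 24 genes 5 rose, among them Ifitm3, Esam and Sult1a1, and 1 fell, the glycosyltransferase gene Gcnt2. Adjusted over the list alone, 9 rose and 2 fell. Ifitm3, an interferon-induced membrane protein gene, stood at 1255 ± 7.9 against 923 ± 83.5 CPM, while the stem cell marker gene Procr differed by 0.07 (SE 0.11). The list's median was 0.29 (camera adjusted p = 2.7e-05, adjusted p = 0.384 with an estimated correlation), and 0.18 without Helios-deficient mouse 2. The aging list held 28 measured genes, of which 4 rose (Selp, Aldh1a1, Clu and Cavin2) and 24 did not pass, and 11 rose and 2 fell when adjusted over the list alone. Its median was 0.57 (camera adjusted p = 1.2e-08, adjusted p = 0.354 with an estimated correlation), and fry gave an adjusted p of 0.0082. Clu, the gene of the secreted chaperone clusterin, stood at 10.5 ± 1.3 against 3.44 ± 0.22 CPM. Esam did not pass without wild-type mouse 1 (adjusted p = 0.101) or 2 (0.199), nor Sult1a1 without wild-type mouse 2 (0.099).

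Of 23 megakaryocyte and platelet genes, Selp and Cavin2 rose and 21 did not pass, with 3 rises when adjusted over the list alone. Both genes also belong to the aging list. Mmrn1 (0.37, SE 0.12) and Gng11 (0.28, SE 0.09) had the next smallest p, with adjusted p of 0.196 and 0.264, and the platelet chemokine gene Pf4 differed by 0.16 (SE 0.77). The list's median was 0.22 (camera adjusted p = 1.5e-04, adjusted p = 0.384 with an estimated correlation). It was 0.14 without Helios-deficient mouse 2, 0.13 without wild-type mouse 1 and 0.04 with equal cells of each cluster per mouse (camera adjusted p = 0.824 for the last). In lymphoid-primed-like cells, described further on, its median was −0.35 (camera adjusted p = 0.0156, adjusted p = 0.350 with an estimated correlation) and in HSC-like cells 0.19 (0.0358, adjusted p = 0.603 with an estimated correlation). For the 14 megakaryocyte-erythroid transcription factors the median was −0.10 (camera adjusted p = 0.243, adjusted p = 0.474 with an estimated correlation), and with equal cells of each cluster per mouse the list passed as lower (median −0.15, camera adjusted p = 0.0130). edgeR called 0 of them and DESeq2 0, with 1 below an unadjusted 0.05 and 1 fall, in Cbfa2t3 (−0.29, SE 0.08), when adjusted over the list alone. Among 16 erythroid genes edgeR called 0, DESeq2 called 1, 9 lay below an unadjusted 0.05 and 7 rose and 2 fell when adjusted over the list alone. Apoe (0.43, SE 0.09) had the smallest p of these, and the list's median was 0.45 (camera adjusted p = 0.152, adjusted p = 0.789 with an estimated correlation). Without wild-type mouse 2 that median was 0.71, and without wild-type mouse 1 it was 0.11 and camera turned direction. Camera also turned direction with equal cells of each cluster per mouse (median 0.02, adjusted p = 0.790).

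The 2 proliferation lists were higher by camera, with no member called. In the G2 and M phase list 50 of 51 genes had positive fold changes, with a median of 0.21 (camera adjusted p = 1.0e-11, adjusted p = 0.384 with an estimated correlation). edgeR called 0 of them and DESeq2 0, with 25 below an unadjusted 0.05 and 20 rises when adjusted over the list alone. Nusap1 (0.42, SE 0.10), Birc5 (0.32, SE 0.08) and Ube2c (0.37, SE 0.09) had the smallest p. In the S phase list 37 of 42 were positive, with a median of 0.12 (camera adjusted p = 2.7e-05, adjusted p = 0.384 with an estimated correlation), 0 called by edgeR and by DESeq2, 11 below an unadjusted 0.05 and 1 rise, in Tipin (0.27, SE 0.07), adjusted over the list alone. With equal cells of each cluster per mouse the medians were 0.05 and −0.01 (camera adjusted p = 0.142 and 0.923). Cluster 6 was led by G2 and M phase genes such as Ube2c, and myeloid-primed-like cells were nearly all called S or G2M. This setting thus also evens out cycling cells between mice, so the smaller medians are partly built in.

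NF-kB target genes were lower as a list of 16, with a median of −0.23 (camera adjusted p = 0.0040, adjusted p = 0.384 with an estimated correlation). The chemokine gene Ccl3 fell over all genes, 15 members did not pass, and 3 fell when adjusted over the list alone. The list did not pass without Helios-deficient mouse 2 (adjusted p = 0.0937), with equal cells of each cluster per mouse (median −0.11, 0.0923) or without cells holding mature cell transcripts (0.119). Oxidative phosphorylation genes (24, median 0.09, camera adjusted p = 0.0027, adjusted p = 0.474 with an estimated correlation) and MYC and nucleolar genes (20, median 0.09, camera adjusted p = 0.022, adjusted p = 0.769 with an estimated correlation) had 0 called members by edgeR and by DESeq2, over all genes tested, and 0 called by edgeR adjusted over the list alone. Below an unadjusted 0.05 lay 7 and 3 of them. Uqcrq (0.19, SE 0.06) and Pa2g4 (0.23, SE 0.07) had the smallest p. Without wild-type mouse 1 the adjusted p of both lists was 0.131, and without Helios-deficient mouse 1 the MYC list had an adjusted p of 0.552 in the other direction.

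The other lists did not pass over all kept cells. Among 18 immediate early and dissociation stress genes Btg2 (−0.72) and Zfp36 (−0.76) fell, also when adjusted over the list alone, and the list's camera adjusted p was 0.604. Neither gene passed without wild-type mouse 2 (adjusted p = 0.0836 and 0.190). The 23 interferon response genes had a median of 0.22 (camera adjusted p = 0.0541, adjusted p = 0.784 with an estimated correlation), with Bst2 (0.22, SE 0.06) first by p. The list passed with equal cells of each cluster per mouse (median 0.25, camera adjusted p = 1.3e-04), without the 30 granulocyte-monocyte cells (0.0162) and without cluster 9, described further on (0.0493). It also passed without Helios-deficient mouse 1 (1.6e-04) and without wild-type mouse 1 (6.4e-06), and camera turned direction without Helios-deficient mouse 2 (median −0.09, adjusted p = 0.705) and without wild-type mouse 2 (median 0.03, 0.558). MHC class II genes (7) and p53 targets (12) each had a camera adjusted p of 0.882, and H2-DMb1 (0.21, SE 0.09) and Cdkn1a (0.62, SE 0.17) came first by p. Cdkn1a passed when adjusted over the list of p53 targets alone. The 4 measured Ikaros family genes had a median of 0.14 (camera adjusted p = 0.0938), with Ikzf1 at 83.0 ± 1.5 against 77.1 ± 4.8 CPM. In these 4 lists edgeR and DESeq2 called 0 genes over all genes tested, with 2, 2, 3 and 2 below an unadjusted 0.05. Adjusted over the list alone, the interferon, MHC class II and Ikaros family lists had 0 calls. With an estimated correlation the Ikaros family list had a camera adjusted p of 0.384, and without Helios-deficient mouse 1 its median was 0.19.

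The cells fell into 10 clusters. By fixed markers, 5 were named HSC-like (561 cells, led by Igkc, Cd74 and Meg3), myeloid-primed-like (655, led by Elane, Ctsg and Mpo, followed by replication genes such as Rrm2, Ung and Uhrf1 of the S phase list), lymphoid-primed-like (490, led by Dntt and Wfdc17), megakaryocyte-primed-like (181, led by Pf4) and erythroid-primed-like (48, led by Car1). At a resolution of 1, 91 cells formed a group with macrophage and B cell markers, and 88 of them lie in the HSC-like cluster. Cluster 1 (831 cells) was led by the interferon-induced genes Ifit1 and Rsad2, cluster 5 (297) by Notch2, cluster 6 (220) by Ube2c, cluster 8 (126) by histone genes and cluster 9 (61) by hemoglobin genes. The stem cell marker gene Procr was also among the leading genes of cluster 9, whose median was 6744 UMIs against 6740 in cluster 1. Whether cluster 9 lies outside the sorted phenotype or holds LSK cells with hemoglobin RNA was not tested. At a resolution of 0.75 the group of 30 cells alone carried the myeloid-primed-like name.

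Lymphoid-primed-like cells made up 10.7% ± 2.4 of the Helios-deficient and 16.4% ± 1.9 of the wild-type cells (mean ± SD, n = 2 mice each), a log2 ratio of −0.58 (SE 0.25, edgeR adjusted p = 0.207). HSC-like cells made up 19.1% ± 0.1 against 14.2% ± 0.7 (log2 ratio 0.43, adjusted p = 0.235) and megakaryocyte-primed-like cells 6.30% ± 0.02 against 4.57% ± 0.81 (0.48, adjusted p = 0.238, and 0.29 without wild-type mouse 1). Myeloid-primed-like cells made up 21.1% ± 5.2 against 17.8% ± 0.8 and erythroid-primed-like cells 1.57% ± 0.70 against 1.28% ± 0.97 (log2 ratios 0.22 and 0.45, adjusted p = 0.431 and 0.50). Among all single-mouse barcodes, clustered and named anew, these log2 ratios were 2.01 and 1.80 (both adjusted p = 0.0509), and the myeloid-primed-like name then fell on 1.48% ± 0.17 against 0.327% ± 0.321 of the cells. Cluster 9 had a log2 ratio of −1.13 (adjusted p = 0.207), which was −1.87 without Helios-deficient mouse 1 and −0.47 without Helios-deficient mouse 2. edgeR called 0 of the 10 clusters, with 2 below an unadjusted 0.05, the lymphoid-primed-like cluster and cluster 9. At a resolution of 1, chosen after seeing the data, the lymphoid-primed-like clusters together had a log2 ratio of −1.06 (adjusted p = 0.0272). A further cluster of 203 cells there, led by Elane and Dntt, was named myeloid-primed-like by its markers, and with it counted as lymphoid-primed-like the log2 ratio was −0.57 (adjusted p = 0.353). At a resolution of 0.25 the HSC-like log2 ratio was −0.01. Without Helios-deficient mouse 1 the myeloid-primed-like log2 ratio was −0.04, and the erythroid-primed-like one was −0.15 without Helios-deficient mouse 2 and −0.26 without wild-type mouse 1.

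**Figure D2:**
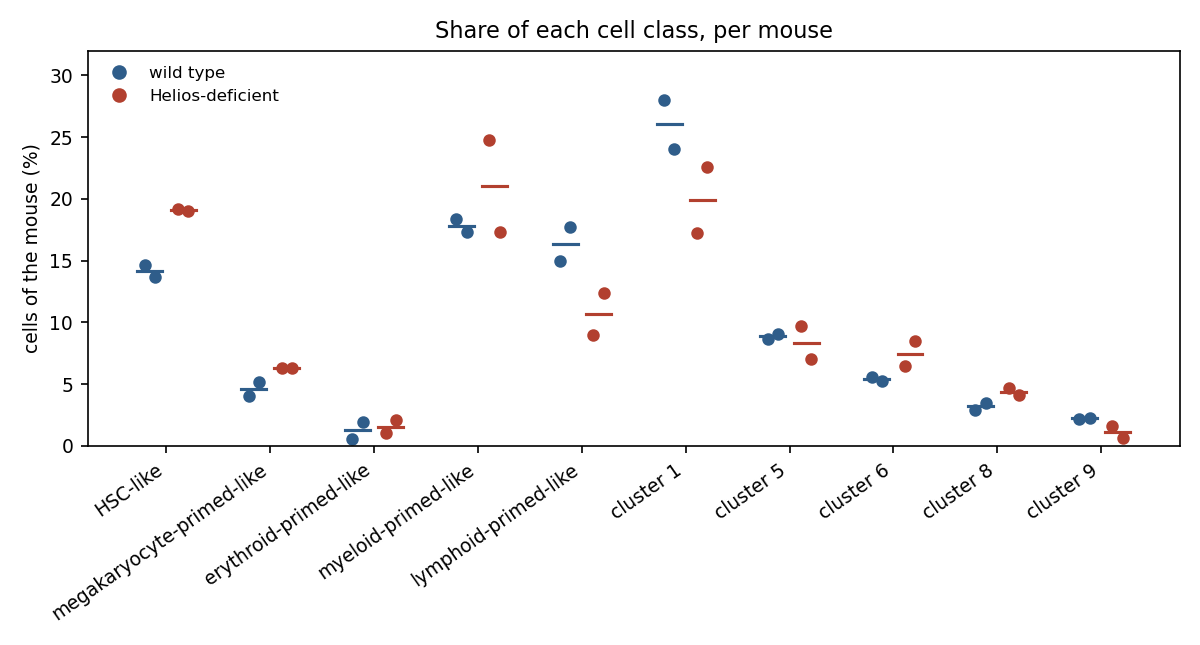
Share of each cell class in percent of a mouse's kept cells, with a point per mouse and a line at each genotype's mean, for 2 wild-type and 2 Helios-deficient mice. HSC-like cells lie near 19.1% in both Helios-deficient mice against 14.2% on average in wild type, and lymphoid-primed-like cells average 10.7% against 16.4%.

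To separate changes within a cell class from changes in its share, genes were tested in 5 classes. Ctse and Acadl fell in every one of the 5. Prtn3 rose in 4 of them, while its log2 fold change in lymphoid-primed-like cells was 0.08 (SE 0.08). Selp rose in HSC-like, cluster 1 and myeloid-primed-like cells.

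In HSC-like cells 6 of 7910 genes rose and 5 fell. Clu (2.60, SE 0.50, edgeR adjusted p = 0.0137), the uncharacterised gene Gm10419 (2.56), Selp (2.15), Aldh1a1 (1.22) and Prtn3 (0.59) had the largest rises. Among the largest falls were Ctse (−2.83, SE 0.30, adjusted p = 1.4e-07), Rpe (−2.07), Edem1 (−1.94) and Acadl (−1.33). The aging list was higher here, with 3 of 19 measured genes called, a median of 0.66 and a camera adjusted p of 7.7e-06 (adjusted p = 0.603 with an estimated correlation). The count of 11 genes was 19 without Helios-deficient mouse 1, 29 without wild-type mouse 1, 36 without wild-type mouse 2 and 4 by DESeq2. Without at least 1 mouse Aldh1a1, Clu, Edem1, Gm10419 and Selp did not pass (adjusted p from 0.117 to 0.941).

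In lymphoid-primed-like cells 92 genes were higher and 41 lower of 8137. Of 41 measured S phase list genes 19 rose, with a median of 0.67 (camera adjusted p = 1.0e-20, adjusted p = 0.350 with an estimated correlation). Among the largest rises were the cyclin gene Ccne2 (3.02, SE 0.57, adjusted p = 0.0013), the repair gene Exo1 (1.67) and Wdr76 (1.14). Ctse (−3.77), Tcrg-C1 (−2.86), a T cell receptor gamma constant region gene, Gm26597 (−1.70), Acadl (−1.58) and Ddit4 (−1.43) had the largest falls. In the cells of the same name at a resolution of 1, 14 genes were called, 12 of them shared, and the S phase list's median was 0.39 with 1 of 30 genes called (camera adjusted p = 0.0019, adjusted p = 0.833 with an estimated correlation). There were 42 and 70 such cells in the Helios-deficient and 178 and 169 in the wild-type mice. Helios-deficient mouse 1 thus lay below the 50 cells required of a class. With the cluster led by Elane and Dntt added, 544 genes were called, 128 of them shared, and the list's median was 0.68 with 29 of 42 genes called (camera adjusted p = 2.3e-19, adjusted p = 0.344 with an estimated correlation). The count of 133 was 83 without Helios-deficient mouse 2, 82 without wild-type mouse 2 and 26 by DESeq2. Exo1, Gm26597 and Wdr76 did not pass without at least 1 mouse (adjusted p up to 0.447).

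The myeloid-primed-like class, whose cells were nearly all called S or G2M as given further on, had 21 genes higher and 8 lower of 9218. F13a1 (3.03, SE 0.45, adjusted p = 0.0478), Hp (2.84), Ms4a3 (2.13), Slpi (1.79) and Tgfbi (1.64), several of them known from granulocytes or monocytes, had the largest rises. Ctse (−3.11), Slc16a11 (−1.44), Gm47283 (−1.20), Rpe (−1.11) and Acadl (−0.91) had the largest falls. Of 19 granulocyte and monocyte list genes 5 rose, with a median of 0.74 (camera adjusted p = 4.5e-09, adjusted p = 0.352 with an estimated correlation). The group of 30 cells lay within this class. Without it 15 genes were called, 8 higher and 7 lower, 12 of the 15 were shared, and Slpi stood at −0.16. The count of 29 was 72 without Helios-deficient mouse 1, 107 without Helios-deficient mouse 2, 47 without wild-type mouse 1 and 13 by DESeq2. Rpe and Tgfbi did not pass without at least 1 mouse (adjusted p = 0.241 and 0.149).

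In cluster 1, 19 genes rose and 22 fell of 9057. Selp (1.88, SE 0.26, adjusted p = 2.5e-10), the chemokine gene Ccl5 (1.78), Ctsg (1.76), S100a4 (1.67) and Gm4951 (1.27) rose most, and Ctse (−3.13), Slc16a11 (−1.91), Ddx4 (−1.65), Acadl (−1.47) and Rpe (−1.21) fell most. The interferon response list had a median of 0.40 here (camera adjusted p = 1.6e-06, adjusted p = 0.712 with an estimated correlation). In cluster 5, 8 genes rose and 6 fell of 6693. The interferon-induced genes Ifitm1 (0.93, SE 0.08, adjusted p = 2.2e-13) and Ifitm3 (0.69) rose, with Smim6 (1.65), Sfi1 (1.55) and Ass1 (0.89). Ctse (−5.14), Slc16a11 (−2.55), Hbb-bt (−2.26), Cpa3 (−2.11) and Acadl (−1.35) fell. Without wild-type mouse 2 the count in cluster 1 was 19 against 41, and without Helios-deficient mouse 2 that in cluster 5 was 26 against 14. DESeq2 called 9 and 3. Ctsg, Ddx4, Gm4951, Rpe and S100a4 in cluster 1 and Acadl, Ass1, Cpa3, Sfi1, Slc16a11 and Smim6 in cluster 5 did not pass without at least 1 mouse.

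Whether a genotype difference itself differed between the 5 classes was tested with an interaction term. It passed in 18 of 9542 genes, and 632 lay below an unadjusted 0.05. Prtn3 was 0.83 higher on the log2 scale in myeloid-primed-like and 0.08 in lymphoid-primed-like cells (interaction adjusted p = 3.2e-06). The myeloid-primed-like value includes the group of 30 granulocyte-monocyte cells. Without them it was 0.47 (SE 0.07) and the interaction did not pass (adjusted p = 0.0689), and it passed in 16 genes, 12 of them shared. Gmnn, which encodes the replication licensing inhibitor geminin, was 1.12 higher in lymphoid-primed-like and −0.10 in myeloid-primed-like cells (adjusted p = 2.6e-05, and 3.9e-05 without the 30 cells). Tyms, the thymidylate synthase gene, stood at 0.84 and −0.20 in the same classes (adjusted p = 0.0155, and 0.0079 without the 30 cells). In thinned myeloid-primed-like cells 97.1% ± 1.1 of Helios-deficient and 96.0% ± 2.4 of wild-type cells were called S or G2M. Without that class the interaction passed in 12 genes, 9 of them shared, among them Gmnn (adjusted p = 0.0055) and Prtn3 (0.0351), and did not pass in Tyms (0.577).

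**Figure D3:**
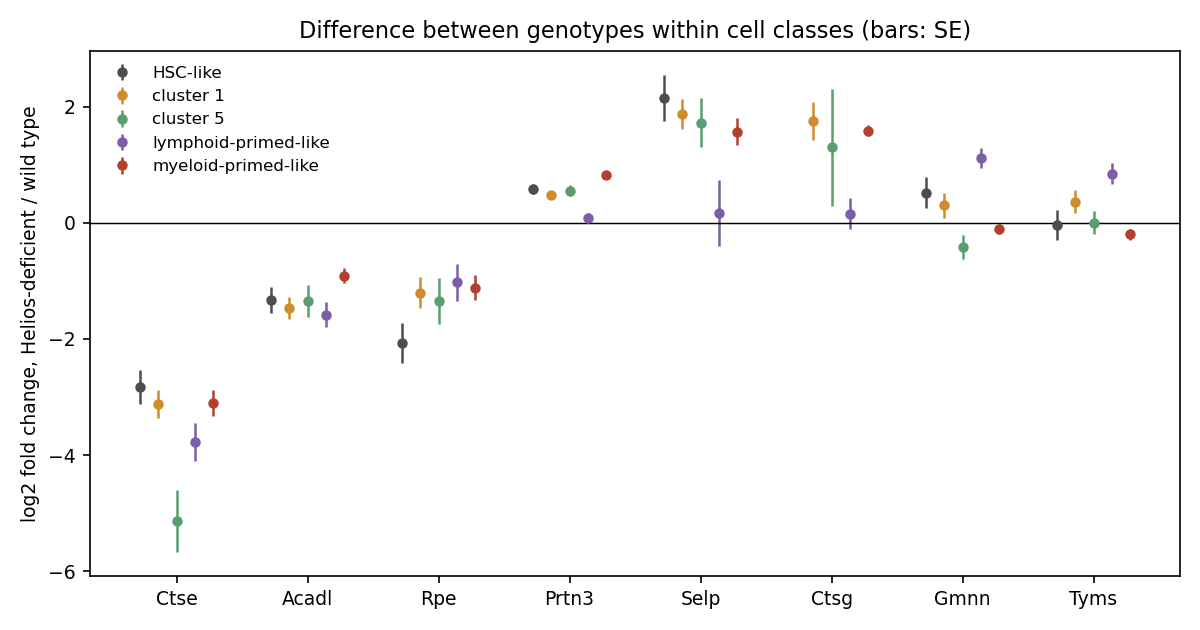
Log2 fold change of Helios-deficient over wild type for 8 genes within 5 cell classes, with points at the edgeR estimate and bars of 1 SE (2 mice per genotype). Ctse and Acadl lie below 0 in every class shown, Prtn3 and Selp lie nearest 0 in lymphoid-primed-like cells, and Gmnn and Tyms lie highest there.

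Cell cycle phases were called from the same lists per cell. In thinned cells 53.05% ± 0.64 of Helios-deficient and 48.2% ± 2.6 of wild-type cells were called S or G2M (mean ± SD, n = 2 mice each, exact permutation p = 0.333, the smallest possible). The G2M calls were 13.9% ± 1.8 against 10.2% ± 1.2 and the S calls 39.1% ± 2.4 against 38.0% ± 1.4. Among lymphoid-primed-like cells S calls made up 47.2% ± 9.0 against 25.6% ± 3.2 (exact permutation p = 0.333). At their own depth the S or G2M calls were 48.8% ± 0.8 against 40.4% ± 0.9. Of 3138 thinned cells 342 lay near a score bound, so these calls are ranges of a score.

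Megakaryocyte and platelet transcripts were also counted per cell. In thinned cells, 80.8% ± 2.0 of Helios-deficient and 81.3% ± 1.6 of wild-type cells had at least 2 UMIs of the list (exact permutation p = 0.667). At a bound of 3 UMIs the shares were 69.5% ± 2.6 and 64.6% ± 1.7, so the direction turned (exact permutation p = 0.333). For cells at their own depth the shares were 93.6% ± 1.0 and 92.1% ± 0.6 at 2 UMIs and 88.6% ± 0.1 and 83.7% ± 1.1 at 3 UMIs. In lymphoid-primed-like cells, which should lack these transcripts, 61.5% (279 of 454) reached 2 UMIs, against 99.4% of megakaryocyte-primed-like and 96.2% of HSC-like cells, all at 5000 UMIs. The shares over all cells therefore include a high background.

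Surface proteins were compared as centred log ratios of the antibody tags. CD41 was at −0.508 ± 0.025 in Helios-deficient and −0.568 ± 0.014 in wild-type mice, and CD48 at 0.597 ± 0.008 against 0.676 ± 0.030 (mean ± SD, n = 2 mice each). Each difference was larger than the spread between mice and had the smallest possible exact permutation p, 0.333. Centred log ratios of a cell's tags have a fixed sum, so the 2 differences are not independent. Within classes both exceeded the larger SD only in cluster 6, cluster 8 and myeloid-primed-like cells. In HSC-like cells they were 0.028 for CD41 and −0.025 for CD48, with larger SDs of 0.055 and 0.039. CD48 turned to 0.031 in lymphoid-primed-like and 0.052 in cluster 9 cells, and CD41 to −0.064 in erythroid-primed-like cells. CD150 differed by 0.024 (exact permutation p = 0.667) and CD135, the protein of Flt3, by −0.004 (p = 1.0 in the same exact permutation test). Within lymphoid-primed-like cells CD135 was at −0.440 ± 0.025 against −0.380 ± 0.032, with both Helios-deficient mice below both wild-type mice, a class looked at after the data were seen. The same order held in cluster 5 (−0.027) and cluster 9 (−0.037). Both Helios-deficient mice lay above both wild-type mice in erythroid-primed-like (0.098), megakaryocyte-primed-like (0.059), cluster 8 (0.045) and cluster 1 (0.022) cells, so the direction differed between classes. Across cells, the tag and the RNA had a Spearman correlation of 0.710 for CD48, 0.207 for CD41 (Itga2b), 0.157 for CD150 (Slamf1) and 0.147 for CD135, and cells are not independent replicates. Median CD135 tags were 37 in cells without a Flt3 UMI and 40 in cells with 2 or more, so the CD135 tag hardly followed its RNA. In the RNA, Slamf1 (0.35, SE 0.22, adjusted p = 0.632), Cd48 (−0.02, SE 0.06, adjusted p = 0.962) and Itga2b (−0.01, SE 0.10, adjusted p = 0.992) did not pass.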

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

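Of the tests described here, the interaction test was planned, the test of the cluster border was set before its result was seen, apart from the added cluster, and the tests of the 30 granulocyte-monocyte cells, of the interaction without 1 class, of free RNA, of depth and of the splits of the mice were chosen only after the results were seen.

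The difference between genotypes itself differed between the 5 cell classes in 18 genes, by the interaction test in edgeR. Among the named and listed genes these were Ly6d (adjusted p = 4.5e-07), Prtn3 (3.2e-06), Cxcl10 (3.2e-06), Gmnn (2.6e-05), Hells (0.0028), Edem1 (0.0069), Mt1 (0.0155), Tyms (0.0155), Hsp90aa1 (0.0155) and S100a4 (0.0355). Ly6d and Cxcl10 differed widely between mice of 1 genotype. Ly6d stood at 117 CPM in HSC-like cells of wild-type mouse 1 and at 0 in those of mouse 2, and at 121 CPM in lymphoid-primed-like cells of Helios-deficient mouse 2 and 2.02 in those of mouse 1. Cxcl10 stood at 100.1 CPM in cluster 1 of Helios-deficient mouse 1 and at 22.7 in that of mouse 2. Edem1 was lower in HSC-like cells (−1.94, SE 0.38) and stood at 0.59 (SE 0.22) in myeloid-primed-like cells. Mt1 was higher in myeloid-primed-like cells (1.16, SE 0.19), Hsp90aa1 in lymphoid-primed-like cells (0.50, SE 0.06) and S100a4 in cluster 1 (1.67, SE 0.27). Without the 30 granulocyte-monocyte cells, all of which lie in the myeloid-primed-like class, the interaction did not pass in Prtn3 (adjusted p = 0.0689), Mt1 (0.348) or Cxcl10 (0.945), and it passed in the other 7 of these genes (up to 0.0370).

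Prtn3 and Ctsg were higher in Helios-deficient cells, as were 3 other members of the granulocyte-monocyte list, while 14 of its 19 measured members were not called. Without the 30 cells of a granulocyte-monocyte stage the list's median log2 fold change was −0.0378, so a larger number of such cells in the Helios-deficient mice may account for the list's median. The 30 cells held Kit at 49.5 and Ly6a at 62.7 CPM, against 91.1 and 148 CPM in all other cells. Fcgr3, a marker that helped to name them, stood at 114 against 1.46 CPM, and S100a8 at 163 against 1.68 CPM. Whether they are late progenitors, sort contaminants or doublets within a mouse was not tested. Prtn3 and Ctsg were still called without these cells, the smaller of their 2 fold changes being 0.39, which argues against them as the whole source for this pair. Free RNA from such cells was compared by fold changes. Without them the log2 fold change in myeloid-primed-like cells lay above that in lymphoid-primed-like cells by 0.39 for Prtn3 and by 0.59 for Ctsg. Only the first exceeded 2 times the summed SE (0.311 and 0.749). Free RNA spread evenly adds an amount rather than a fold, so this comparison cannot decide. Ctsg in cluster 1 stood at 15.5 and 35.02 CPM in the Helios-deficient mice, which bounds that amount. Myeloid-primed-like cells without the 30 held 173.4 CPM over all mice, with a log2 fold change of 0.75 (SE 0.11). These values argue against free RNA as the whole source of the Ctsg rise there. For Prtn3 free RNA stays open. A change in expression within progenitors also stays open as a hypothesis.

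The S phase list was higher in Helios-deficient lymphoid-primed-like cells (camera adjusted p = 1.0e-20, adjusted p = 0.350 with an estimated correlation), with Gmnn, Hells and Tyms among the genes whose difference varied between classes. Myeloid-primed-like cells were nearly all called S or G2M in both genotypes, which left such calls little room to rise there, and without that class the interaction passed in Gmnn (adjusted p = 0.0055) but not in Hells (0.534) or Tyms (0.577). Deeper cells in the Helios-deficient mice do not account for it, since after thinning to 1 depth the S phase calls still differed by 21.5 percentage points, more than 2 times the larger SD between mice. Where the cluster's border lies could matter. At a resolution of 1 the list was still called (camera adjusted p = 0.0019, adjusted p = 0.833 with an estimated correlation). Its median was 0.39 rather than 0.67, a value between the bounds set in advance, with 1 of 30 genes called. Helios-deficient mouse 1 had 42 cells there, below the 50 required of a class, so fewer calls can also reflect fewer cells. With a cluster led by Elane and Dntt added the median was 0.68, with 29 of 42 genes called. A faster cycle of these cells and a different mix of cells inside the cluster cannot be told apart from these values.

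The 4 mice can be split into equal pairs in 3 ways. The real split called 92 genes, 1 split of the 3 gave as many, and the highest of the other splits called 2. With 3 splits a share under 0.05 cannot be reached.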

How the results depend on the processing

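The settings marked in the methods as added after seeing the data were chosen only then, and all other settings were planned. Among named genes over all cells, 937 values under other settings kept direction and side of the threshold, 59 lost and 25 gained the call, and 6 reversed. Without 1 mouse these numbers were 266, 15, 39 and 4. Of the 20 genes with the largest changes, 20 passed under RLE scaling, 17 in thinned cells, 15 without the robust option and 11 by DESeq2. In counts simulated at the depth and number of these mice, 79 of 100 genes changed 1.5-fold were recovered, and depth was not varied there. This recovery holds for the simulated counts, whose changed genes lay above a mean of 10 CPM, not for every gene tested. No paired analysis was possible because the labels give the mice of the 2 genotypes no shared number, litter or batch. Unless a sentence says otherwise, the cause of a change was not tested.

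Over all cells, 92 genes became 296 without a count filter, 57 without the robust option, 144 with all single-mouse barcodes, 44 with equal cells of each cluster per mouse, 35 by DESeq2 and 126 to 565 without 1 mouse, where 1 mouse carries a genotype. The 10 lists called became 6 with equal cells of each cluster (4 of the 10, with megakaryocyte-erythroid transcription factors and interferon response newly called), 6 (all among the 10) without cells holding mature cell transcripts, 0 with an estimated correlation (1 below an unadjusted 0.05) and 1 by fry. Camera directions reversed with equal cells of each cluster for erythroid (adjusted p = 0.790), S phase (0.923), MHC class II (0.730) and p53 targets (0.790). Without cells holding mature cell transcripts they did for megakaryocyte-erythroid transcription factors and p53 targets (both 0.906), and without the 30 granulocyte-monocyte cells for their list (0.945). Without 1 mouse, directions reversed in 7 lists, and camera's adjusted p ranged from 0.285 to 0.733 for MHC class II, 3.3e-05 to 0.552 for MYC and nucleolar, 0.115 to 0.881 for immediate early and dissociation stress and 6.4e-06 to 0.705 for interferon response. It ranged from 1.1e-05 to 0.782 for erythroid, 0.558 to 0.991 for p53 targets and 0.0956 to 0.894 for megakaryocyte-erythroid transcription factors.

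For class shares, 1 cluster passed at a resolution of 1, with a lymphoid-primed-like log2 ratio of −1.06 (−0.57 and 0 passing with the cluster led by Elane and Dntt counted in), and the HSC-like ratio was −0.0083 at 0.5 times the main resolution. Without 1 mouse the myeloid-primed-like ratio ranged from −0.0433 to 0.47 and the erythroid-primed-like one from −0.26 to 1.44. Within HSC-like cells 11 genes became 4 by DESeq2, 26 without a count filter and 12 to 36 without 1 mouse. Within cluster 1, 41 became 9 by DESeq2 and 19 to 45 without 1 mouse, and within cluster 5, 14 became 3 and 11 to 26. Within lymphoid-primed-like cells 133 became 26 by DESeq2, 14 at a resolution of 1, 544 there with the cluster led by Elane and Dntt, and 82 to 146 without 1 mouse. Within myeloid-primed-like cells 29 became 13 by DESeq2, 65 without a count filter, 15 without the 30 cells and 40 to 107 without 1 mouse. The difference in cells with megakaryocyte list UMIs turned from −0.46 to 4.95 percentage points at 3 UMIs and to 1.45 at 2 UMIs and own depth. CD135 turned from −0.004 to 0.015 with logs per 10000 tags. Uncalled genes also reversed: Itga2b with all single-mouse barcodes (0.0624), without cells holding mature cell transcripts (0.15), without the 30 cells (0.0293) and without 1 mouse (−0.15 to 0.10), Gfi1b with all single-mouse barcodes (0.0031), Cd48 with equal cells of each cluster (0.0346) and without 1 mouse (−0.0477 to 0.0204), and Cd74 without cells holding mature cell transcripts (0.20). Slpi in myeloid-primed-like cells stood at −0.16 without the 30 cells.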

Other observations

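The tests in this part were chosen only after the results were seen.

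Outside the fixed lists, Ltb, Tcrg-C1 and Sox4 were also lower over all LSK cells. Ltb, the lymphotoxin beta gene, stood at 116 ± 1.0 CPM in Helios-deficient and 174 ± 3.7 CPM in wild-type mice (edgeR adjusted p = 3.9e-05, n = 2 mice each). Tcrg-C1, a T cell receptor gamma constant region gene, stood at 1.44 ± 0.19 against 7.13 ± 0.57 CPM (adjusted p = 1.9e-04). The transcription factor gene Sox4 changed by −0.33 (adjusted p = 0.0033). These 3 genes were picked after their values were seen and were not tested as a group, and Ltb was also among the leading genes of cluster 9.

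Acadl, Rpe and Lancl1, which lie within 3 Mb of Ikzf2, were lower in Helios-deficient cells. Different shares of cell classes do not account for this, since the median log2 fold change of the 3 genes lay at −0.91 or below in each of the 5 classes. A chromosome segment linked to Ikzf2 that differs between the mouse lines is a candidate explanation that these values do not decide. The 3 genes prompted it, so they cannot test it, and among the uncalled genes 5 of 66 within 10 Mb of Ikzf2 lay below an unadjusted 0.05 against 1053 of 10988 elsewhere (Fisher's exact test, two-sided p = 0.833), an odds ratio of 0.77 (95% interval 0.24 to 1.91). Control of these genes by Helios itself or by the deleted sequence stays open too and was not tested, and the labels do not name the strain background. Ctse, Selp and Cavin2 also lie on chromosome 1, beyond 10 Mb of Ikzf2, and a linked segment was not tested for them.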
